A study of Arabidopsis thaliana with 2 samples.

How the data were processed

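Total RNA of whole Arabidopsis thaliana seedlings was compared on 2 two-colour Agilent 60-base oligonucleotide arrays, which the labels call biological replicates 1 and 2. Per the labels, Col-0 seedlings were grown in 16 h of light at 22 C and 8 h of dark at 20 C. At 14 days they were exposed for 6 h in air-tight chambers to 3.1 ppb safranal in the air, or served as controls, and 500 ng of RNA was labelled per sample. Both arrays lay on 1 slide, so the slide is no batch, and both had the same dye orientation, so that a dye effect and an effect of the exposure could not be told apart. No paired analysis was possible because there was only 1 comparison, and each array already sets 1 exposed against 1 control RNA.

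The deposited scanner files hold, per the file headers, the mean signal and the median local background of each spot and dye as raw intensity values, and processed intensity values that Agilent Feature Extraction had background-subtracted and dye-normalized with a LOWESS curve. The same deposited files hold the log10 ratio of the processed Cy5 over Cy3 signals, set to 0 for spots dim in both dyes, and other values that are 0 or 1 marks for spots well above background, saturated or uneven. The submitters' processing notes name Feature Extraction 8.5.1.1, while the header of the replicate 1 file names 10.5.1.1. The replicate 2 file lacks that header block and gives many columns to fewer digits. The deposited value table is in log10 as well, and it is the negative of the ratio in the scanner files (Pearson correlation across spots 0.9996 for each array, with 99.95% and 99.96% of spots within 0.006). It therefore holds Cy3 over Cy5.

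Each array held 45220 spots, of which 43803 were gene spots of 43603 distinct probes. Of these probes, 37540 named 1 gene locus, 873 named several and 5190 named none. The median mean signal was 169 in Cy3 and 231 in Cy5 on replicate 1, and 159 and 263 on replicate 2, over median backgrounds of 34, 55.5, 33 and 54. On replicate 1, 60.3% of gene spots were well above background in Cy3 and 67.1% in Cy5, and on replicate 2 the shares were 61.4% and 70.7%. No gene spot was saturated, and 336 and 506 gene spots marked as uneven or as outliers were left out. The number of arrays limits the precision of every value. None of 153 negative control spots was well above background.

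Mean signals were corrected with the background medians by normexp with an offset of 50, and log2 Cy5/Cy3 ratios were normalized within each array by loess (span 0.3) with control spots at weight 0. Repeated spots of a probe were averaged. A probe was tested if it was well above background in at least 1 dye on both arrays, which 26218 probes with 1 locus were, and the brightest probe stood for each gene. This gave 19524 genes, 5309 of them on more than 1 tested probe. Probes with several loci (516 bright enough) and with no locus (2033) were left out of the comparison. The mean log2 ratio of each gene was tested against 0 with an intercept in limma (lmFit and eBayes), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The arrays leave 1 residual degree of freedom, to which eBayes added a prior of 2.63. Errors are the SD of both arrays. Genes at least 2-fold apart in one direction on both arrays were counted without a test. Symbols came from the RefSeq annotation, which held 19364 of the genes (99.2%), and positions from the probe annotation of the arrays, on the ath1 build that the header names.

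The genes named were chosen by a rule: in each dye direction the 15 with the largest mean log2 ratio among those past the threshold, at least 2-fold on both arrays and well above background in both dyes on both, and up to 4 members of each list with the lowest p. This gave 121 genes, 92 of them from the lists and 1, HRE2, under both parts. Other members named in the text were chosen after their values were seen. They are HSP18.2, HSFA3, AT1G52560 and GSH1, which did not pass, the root markers PHO1, PLT1 and WOX5, which did not pass either, and HSFA2, RAB18, EXPA10, HRE1, GSH2, GSTF2, GSTF3, GSTF6 and GSTU12, which did. The members named from gene families were also picked after their values were seen, as were the examples named from a second list of clock genes, a list that was itself written before its values were examined. For a gene dim in one dye on both arrays, the fold was taken against the 95th percentile of the normalized signals of gene spots not well above background in that dye and array, or against the gene's own signal where that was higher, and its mean over the arrays is written as at least N-fold. This floor was chosen after the data were examined, in place of the lowest signal counted as well above background, which lay under the signals of most of these genes and so bounded little. The 23 gene lists had 360 members, of which 332 were tested, 27 had only dim or left-out spots and 1 only probes with several loci. Lists were tested with limma camera at a preset correlation of 0.01 and adjusted over the lists, with camera at an estimated correlation and fry beside it. At the preset correlation genes act as the replicates, so the p covers the spread between genes, not between arrays or seedlings. The estimated correlation was 0.22 for heat shock, 0.50 for detoxification and 0.68 for photosynthesis genes, but -0.04 for jasmonate genes. That estimate, the test that uses it and fry rest on 1 residual degree of freedom and have little power. Groups, the 23 lists, the rule, the tests of genes and of these lists and the alternatives were fixed before the data were examined, and the tests chosen later are named with their results.

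The alternatives were no background correction, an offset of 0, the Agilent processed signals, the Agilent log ratio, the table of deposited values, median centring in place of loess, scaling between arrays, no filter on dim probes, a filter on both dyes, the mean over a gene's probes, outlier spots kept, an intensity trend with a robust prior, an ordinary 1-sample test and each replicate left out. Nominal ratios of the single spike-in transcripts were not in the files, so the planned slope against them could not be computed under each alternative. Per the file header of replicate 1, Feature Extraction found a slope of observed on expected spike-in log ratios of 0.882, with a correlation of 0.991, and the replicate 2 file gives no such value. In place of the planned slope, that of replicate 1 on replicate 2 was taken over 10 spike-in transcripts with 32 spots each, and it was 0.904. Neither slope shows which dye carried the RNA of the exposed seedlings.

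The steps were tested on simulated data with 19524 genes. With 225 genes changed, 25 of them as a shifted list, 0% of genes changed 1.5-fold and 0% of those changed 2-fold were called, against 92% at 4-fold and 98% at 8-fold, and 16 of 111 calls were false (14.4%, above the 5% set by the threshold). With 6025 genes changed, 61.4%, 93.8%, 98.9% and 99.7% were called, and 197 of 5527 calls were false (3.56%). The shifted list was called in both simulations and none of 22 unchanged lists was. The simulated data had no dye effect of single probes. The variance of each gene was drawn from the prior that limma had fitted to these arrays, and was equal on both arrays. The share of false calls therefore holds only for noise of that form, which the model assumes. Noise was drawn independently for each gene, so the list result does not cover lists whose members are correlated. R 4.3.3 with limma 3.58.1, data.table (version 1.17.8) and jsonlite 2.0.0 and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 were used.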

Results

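Arabidopsis thaliana seedlings of the Col-0 accession, 14 days old, were kept for 6 h in air with 3.1 ppb safranal and compared with control seedlings. Safranal is the volatile monoterpene aldehyde behind the scent of saffron. In the Cy3 channel, 24 of 28 heat shock genes, 34 of 42 detoxification genes and 6 of 8 sulfate and glutathione genes were higher, and the largest ratio was 55.7-fold for AT1G71000, which has a DNAJ domain (log2 -5.80 ± 0.85, SD, n = 2 arrays). In the Cy5 channel, 21 of 24 photosynthesis genes, 11 of 15 glucosinolate genes, 15 of 26 jasmonate genes and 9 of 18 cell wall genes were higher, and the largest ratio was 37.7-fold for AT1G66180, an aspartyl protease (log2 5.23 ± 0.01). Each of these 7 lists passed with limma camera at a preset correlation, where genes act as the replicates, and none with an estimated correlation (adjusted p = 0.848). The latter test rests on 1 residual degree of freedom, and its lowest unadjusted p over the lists was 0.125 (camera). It has little power to call a list, and the former does not cover the spread between seedlings. The Cy3 channel is likely that of the safranal-exposed seedlings, but the sources do not fully settle it. The channel labels give Cy3 to safranal and Cy5 to the control on both arrays, while the labelling protocol, which names another compound, gives Cy3 to the control and Cy5 to the treated RNA. The deposited value table holds Cy3 over Cy5, the order the titles imply under the channel labels, but it may have been built from those same labels. All values below are therefore given by dye, as log2 of Cy5 over Cy3, so that a negative value means more transcript in Cy3.

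The question the comparison addresses is which transcripts differ between safranal-exposed and control seedlings. Of 19524 genes tested, 3069 were higher in Cy3 and 3789 in Cy5 at an adjusted p under 0.05 (limma), together 35.1% of the genes. Without regard to a test, 1112 genes were at least 2-fold higher in Cy3 on both arrays and 1443 at least 2-fold higher in Cy5 on both, against 1 gene 2-fold apart in opposite directions. Across genes, which are not independent replicates, the log ratios of the arrays had a Pearson correlation of 0.918 and a Spearman correlation of 0.909. Centring each array on its median in place of an intensity curve moved the median log2 ratio of all genes from 0.05 to 0.45 and gave 1370 genes higher in Cy3 and 9004 higher in Cy5, with 540 and 3391 at least 2-fold apart on both arrays, while the Agilent processed signals gave 1849 and 2956 genes 2-fold apart. An ordinary 1-sample test per gene and, in limma, a scaling of both arrays to one spread each left 0 genes past the adjusted threshold, with 3576 and 5141 genes at an unadjusted p under 0.05 against 9671.

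**Figure D1:**
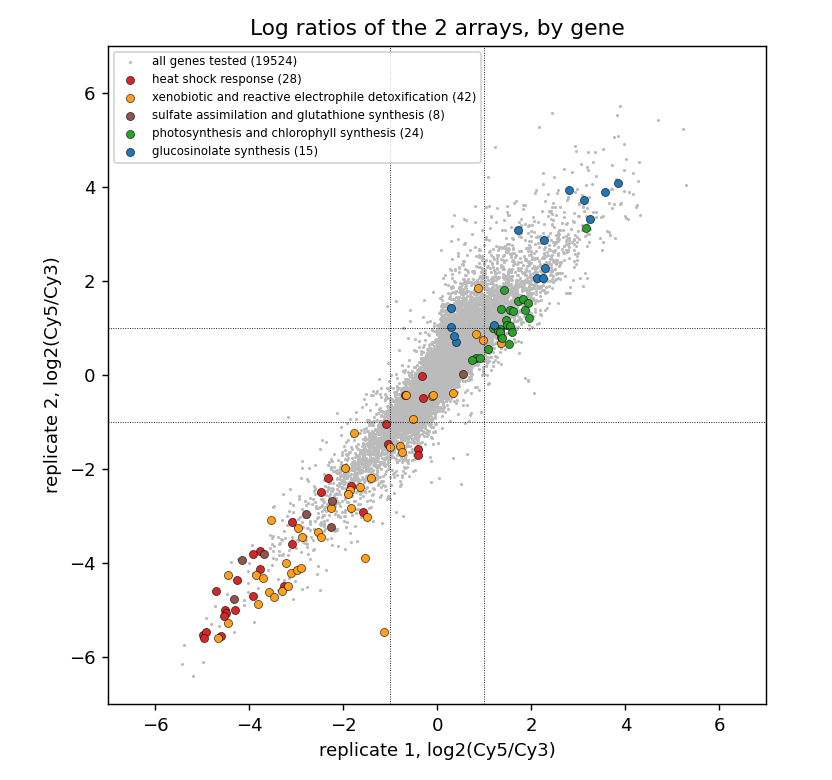
Log2 Cy5/Cy3 ratios of replicate 1 (horizontal axis) and replicate 2 (vertical axis), 1 point per gene tested, with members of 5 gene lists in colour and dotted lines at a 2-fold ratio. Heat shock, detoxification and sulfate genes lie mostly toward the lower left (higher in Cy3) and photosynthesis and glucosinolate genes toward the upper right (higher in Cy5); 2555 genes lie beyond 2-fold in one direction on both arrays and 1 gene in opposite directions.

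Several of the 15 genes with the largest ratios in the Cy3 direction encode chaperones. HSP70 (AT3G12580), a cytosolic chaperone of the heat response, had a log2 ratio of -5.27 ± 0.45 (SD, n = 2 arrays), or 38.6-fold higher in Cy3. Its probe lies on chromosome 3 at 3991609 to 3991668 in the ath1 build named by the file header. The cytosolic small heat shock proteins AT1G59860, AT2G29500 and AT1G07400 had ratios of -5.56 ± 0.25, -5.18 ± 0.39 and -4.84 ± 0.41. The mitochondrial small heat shock protein AT5G51440 stood at -5.07 ± 0.68 and ROF2 (AT5G48570), an FK506-binding peptidyl-prolyl isomerase, at -5.25 ± 0.39. AT1G71000 also belongs to this set. Genes of small-molecule modification made up a second set: the glycosyltransferase UGT74E2 had a ratio of -5.13 ± 0.66, the tau-class glutathione transferase GSTU25 of -4.86 ± 0.58, and AT5G22140, annotated as a pyridine nucleotide-disulphide oxidoreductase, of -5.79 ± 0.50. AT1G60750, annotated on the array as an aldo/keto reductase pseudogene, stood at -5.55 ± 0.80. The remaining 4 were HRE2, a transcription factor of the low-oxygen response (-4.89 ± 0.80), ACA2, an alpha carbonic anhydrase (-5.05 ± 0.17), and AT1G12030 and AT5G54165, which have no described function on the array (-5.05 ± 0.35 and -4.99 ± 0.48). The adjusted p of these 15 genes lay between 0.00485 and 0.00582 in the limma fit.

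In the Cy5 direction AT1G66180, with its probe on chromosome 1 at 24652192 to 24652251, had the largest ratio. The peroxidases AT4G30170, AT5G39580 and AT5G19890 had ratios of 4.81 ± 1.29, 4.67 ± 0.89 and 4.06 ± 0.98. Cell wall genes were RHS13, a root hair gene of the pollen Ole e 1 and extensin family (4.47 ± 0.87), XTH9, a xyloglucan endotransglucosylase/hydrolase (4.16 ± 0.27), and the beta-galactosidase BGAL4 (4.01 ± 0.22). KCS12, a ketoacyl-CoA synthase of very-long-chain fatty acid elongation, stood at 4.44 ± 0.66, the oligopeptide transporters OPT1 and OPT6 at 4.21 ± 0.10 and 4.09 ± 0.53, and AKN2, a kinase of adenosine phosphosulfate, at 4.30 ± 0.42. AT3G19850, of the NPH3 family, had a ratio of 4.17 ± 0.90, and AT5G44585, AT2G22122 and AT1G19380, with no described function, had ratios of 5.06 ± 0.52, 4.41 ± 0.17 and 4.23 ± 0.11. Their adjusted p lay between 0.00485 and 0.0102 (limma). Other probes of AT4G30170, AT5G39580 and XTH9 gave smaller ratios of the same sign, 1.5, 3.61 and 3.05. Among 129 named or listed genes with another tested probe, 14 had a probe more than 1 log2 unit away. Of the 96 such genes that passed, 1 had another probe of the opposite sign.

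**Figure D2:**
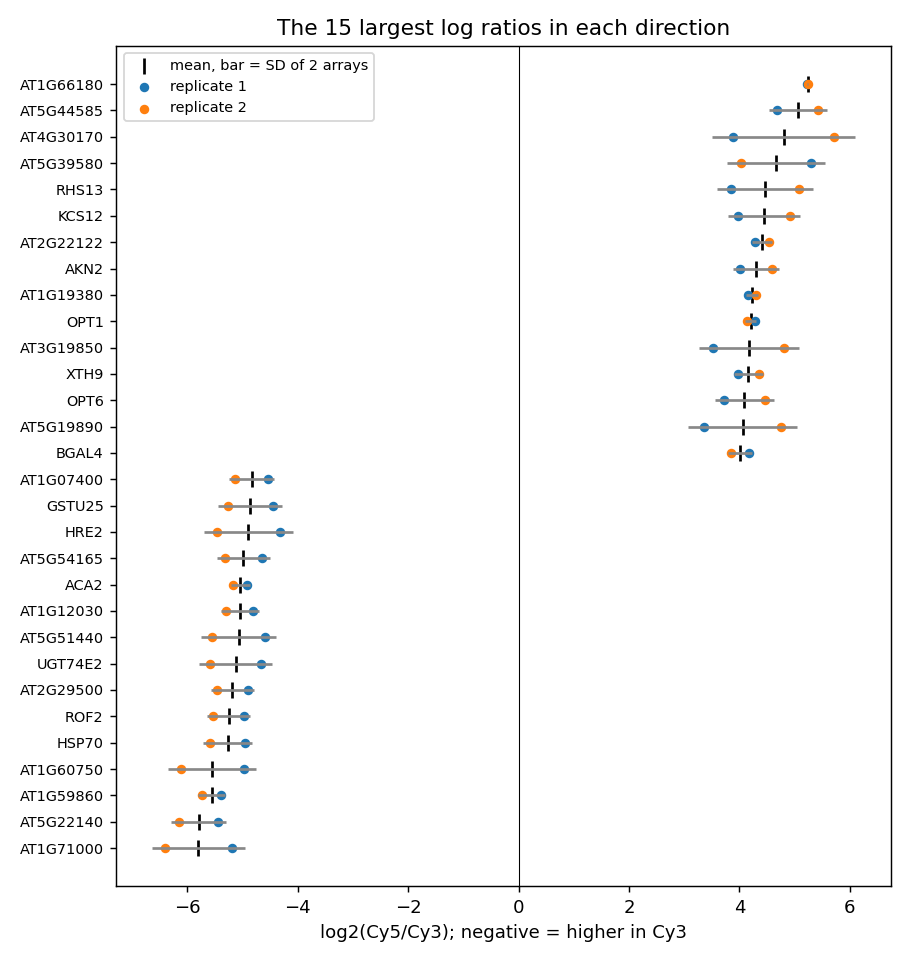
The 15 genes with the largest mean log2 Cy5/Cy3 ratio in each direction that passed the test and were well above background in both channels, with the value of each array as a point, the mean as a tick and the SD of the 2 arrays as a bar. The means run from -5.80 (AT1G71000) to -4.84 (AT1G07400) on the Cy3 side and from 4.01 (BGAL4) to 5.23 (AT1G66180) on the Cy5 side.

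Of 28 heat shock genes tested, 24 were higher in Cy3 and none in Cy5 (adjusted over the list alone, 27 and 0), with a median log2 ratio of -3.81 (camera, adjusted p = 3.92e-15; adjusted p = 0.848 with an estimated correlation). The transcription factor HSFA2 and the coactivator MBF1C, regulators of the heat response, had ratios of -4.76 ± 0.35 and -4.65 ± 0.08 (SD, n = 2 arrays), the mitochondrial chaperone HSP23.6-MITO of -4.30 ± 0.06 and the co-chaperone BAG6 of -3.76 ± 0.01. HSP18.2 (-0.39 ± 0.13) and HSFA3 (-0.17 ± 0.23) were among the 4 members that did not pass. AT1G52560, another of them, was not well above background in Cy5 and was at least 1.67-fold higher in Cy3, with an adjusted p of 0.0935 (limma).

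Detoxification genes, which conjugate, reduce or export foreign and reactive compounds, were higher in Cy3 for 34 of 42 members and higher in Cy5 for 4 (34 and 4 adjusted over the list alone). Their median was -2.63 (camera, adjusted p = 2.14e-11, or adjusted p = 0.848 with an estimated correlation), with -1.94 on replicate 1 and -3.05 on replicate 2. The cytochrome P450 CYP81D8 stood at -4.36 ± 0.14, the transporter ABCB4 at -4.05 ± 0.27, the sterol desaturase CYP710A1 at -3.10 ± 0.22 and GSTU22 at -4.01 ± 0.42. The 4 members higher in Cy5 were glutathione transferases: GSTF2 (0.87 ± 0.16), GSTF3 (0.85 ± 0.04) and GSTF6 (1.02 ± 0.47) of the phi class and GSTU12 (1.35 ± 0.70) of the tau class.

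Sulfate assimilation and glutathione genes were higher in Cy3 for 6 of 8 members and in Cy5 for 1 (6 and 1 adjusted over the list alone). Their median was -2.82 (camera, adjusted p = 0.0020, or adjusted p = 0.848 with an estimated correlation). LSU1, LSU2 and SDI1, known as markers of sulfur shortage, had ratios of -4.54 ± 0.31, -3.75 ± 0.08 and -4.05 ± 0.16, and the adenylylsulfate reductase APR1 of -2.88 ± 0.12. The glutathione synthetase GSH2 lay on the Cy5 side (1.07 ± 0.39), and GSH1, the enzyme that commits cysteine to glutathione, had a ratio of 0.28 ± 0.38 and did not pass.

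Oxidative stress and mitochondrial retrograde genes were higher in Cy3 for 8 of 17 members and in Cy5 for 1 (9 and 2 adjusted over the list alone). Their median was -0.69 (camera, adjusted p = 0.00435, or adjusted p = 0.867 with an estimated correlation). It was -0.36 on replicate 1 and -0.76 on replicate 2. With median centring it was -0.16 against 0.45 for all genes (camera, adjusted p = 0.00068), with 5 members higher in Cy3 and 3 in Cy5. ZAT12, a zinc finger factor of oxidative stress, had a ratio of -4.09 ± 0.11, the alternative oxidase AOX1A of -3.48 ± 0.16 and the external NAD(P)H dehydrogenase NDB2 of -3.78 ± 0.36. The catalase CAT3, a clock-regulated gene, lay on the other side at 2.85 ± 0.14, and its 8 other probes gave values from 0.35 to 3.15. Abscisic acid and dehydration genes were higher in Cy3 for 10 of 16 members and in Cy5 for 2 (12 and 2 adjusted over the list alone). Their median was -1.05 (camera, adjusted p = 0.000181, or adjusted p = 0.848 with an estimated correlation). With median centring it was -0.48 against 0.45 for all genes (camera, adjusted p = 7.4e-06). Among them the phosphatase ABI2, which dampens the response to the hormone, stood at -3.54 ± 0.36, the dehydrins LTI30 and COR47 at -2.71 ± 0.18 and -1.64 ± 0.06 and the transcription factor ABF3 at -1.43 ± 0.03, while the dehydrin RAB18 stood at 1.33 ± 0.07.

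Photosynthesis and chlorophyll genes were higher in Cy5 for 21 of 24 members and in Cy3 for none (24 and 0 adjusted over the list alone). Their median was 1.29 (camera, adjusted p = 1.63e-08, or adjusted p = 0.848 with an estimated correlation). The largest ratio was that of PORB, a protochlorophyllide reductase (3.14 ± 0.03, SD, n = 2 arrays; 3 other probes gave values from 0.85 to 3.10). Root markers, with a median of 1.11, lay on the same side. RBCS2B, a small subunit of Rubisco, stood at 1.65 ± 0.09 and the antenna proteins LHCB4.2 and LHCA1 at 1.72 ± 0.15 and 1.38 ± 0.03. With the Agilent processed signals 13 of the 24 photosynthesis genes were higher in Cy5, with a median of 1.01 (camera, adjusted p = 0.00805). Glucosinolate genes were higher in Cy5 for 11 of 15 members and in Cy3 for none (14 and 0 adjusted over the list alone). Their median was 2.28 (camera, adjusted p = 6.11e-07, or adjusted p = 0.848 with an estimated correlation). CYP79B2 and CYP83B1 of the indolic branch had ratios of 3.97 ± 0.17 and 3.73 ± 0.23, CYP83A1 of the aliphatic branch 3.28 ± 0.05 and the C-S lyase SUR1 2.28 ± 0.01. Of the 15, 4 were not well above background in Cy3 on either array, and with those at their bounds the median was the same, 2.28.

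Jasmonate genes were higher in Cy5 for 15 of 26 members and in Cy3 for none (17 and 0 adjusted over the list alone). Their median was 1.15 (camera, adjusted p = 2.98e-05, or adjusted p = 0.848 with an estimated correlation). The vegetative storage proteins VSP1 and VSP2, jasmonate-induced in leaves, stood at 2.29 ± 0.33 (3 other VSP1 probes gave values from 0.48 to 2.51) and 2.04 ± 0.32, the repressor JAZ2 at 1.35 ± 0.01 and the transcription factor ORA59 at 1.55 ± 0.22. Ethylene genes were higher in Cy5 for 6 of 10 members and in Cy3 for 1 (7 and 1 adjusted over the list alone). Their median was 1.18 (camera, adjusted p = 0.0353, or adjusted p = 0.848 with an estimated correlation), with 0.77 on replicate 1 and 1.37 on replicate 2. ACO4, of ethylene synthesis, stood at 1.57 ± 0.31, the receptor ETR2 at 1.54 ± 0.37 and the F-box protein EBF2 at 1.16 ± 0.32, while the synthase ACS6 stood at -1.65 ± 0.12. The call of this list was lost with the Agilent processed signals (camera, adjusted p = 0.0947) and with median centring. The medians there were 1.33 and 1.68, against 0.03 and 0.45 for all genes, with 7 and 9 members higher in Cy5. Its adjusted p ranged from 0.00886 to 0.111 over 11 alternatives (camera).

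Cell wall expansion genes were higher in Cy5 for 9 of 18 members and in Cy3 for 1 (10 and 1 adjusted over the list alone). Their median was 1.2 (camera, adjusted p = 0.00122, or adjusted p = 0.848 with an estimated correlation), with 0.61 on replicate 1 and 1.54 on replicate 2. The xyloglucan endotransglucosylases XTH15, XTH4 and XTH24 stood at 3.98 ± 0.13, 2.66 ± 0.25 and 1.85 ± 0.21 and the expansin EXPA11 at 2.44 ± 0.39, while EXPA10 stood at -1.44 ± 0.56. A second probe gave 0.54 for XTH15 and 1.28 for XTH4. Root markers were higher in Cy5 as well, for 7 of 13 members against none in Cy3 (7 and 0 adjusted over the list alone). Their median was 1.11 (camera, adjusted p = 0.0116, or adjusted p = 0.848 with an estimated correlation), with 0.81 on replicate 1 and 1.41 on replicate 2. The endodermal CASP1 stood at 2.36 ± 0.58, the root hair expansin EXPA7 at 2.30 ± 0.58 and the aquaporin TIP2;3 at 1.53 ± 0.49. COBL9, of root hairs, was not well above background in Cy3 and was at least 4.80-fold higher in Cy5, with an adjusted p of 0.0175 (limma). With median centring neither list passed. The medians there were 1.67 for cell wall expansion and 1.49 for root markers, against 0.45 for all genes, with 12 and 9 members higher in Cy5. The adjusted p ranged from 1.09e-06 to 0.0818 for cell wall expansion and from 1.28e-06 to 0.0774 for root markers over 11 alternatives (camera). Of the guard cell markers, 2 of 5 were higher in Cy5 (3 adjusted over the list alone), MYB60 at 1.40 ± 0.14 and FAMA at 1.36 ± 0.20, and the list did not pass (camera, adjusted p = 0.0875).

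**Figure D3:**
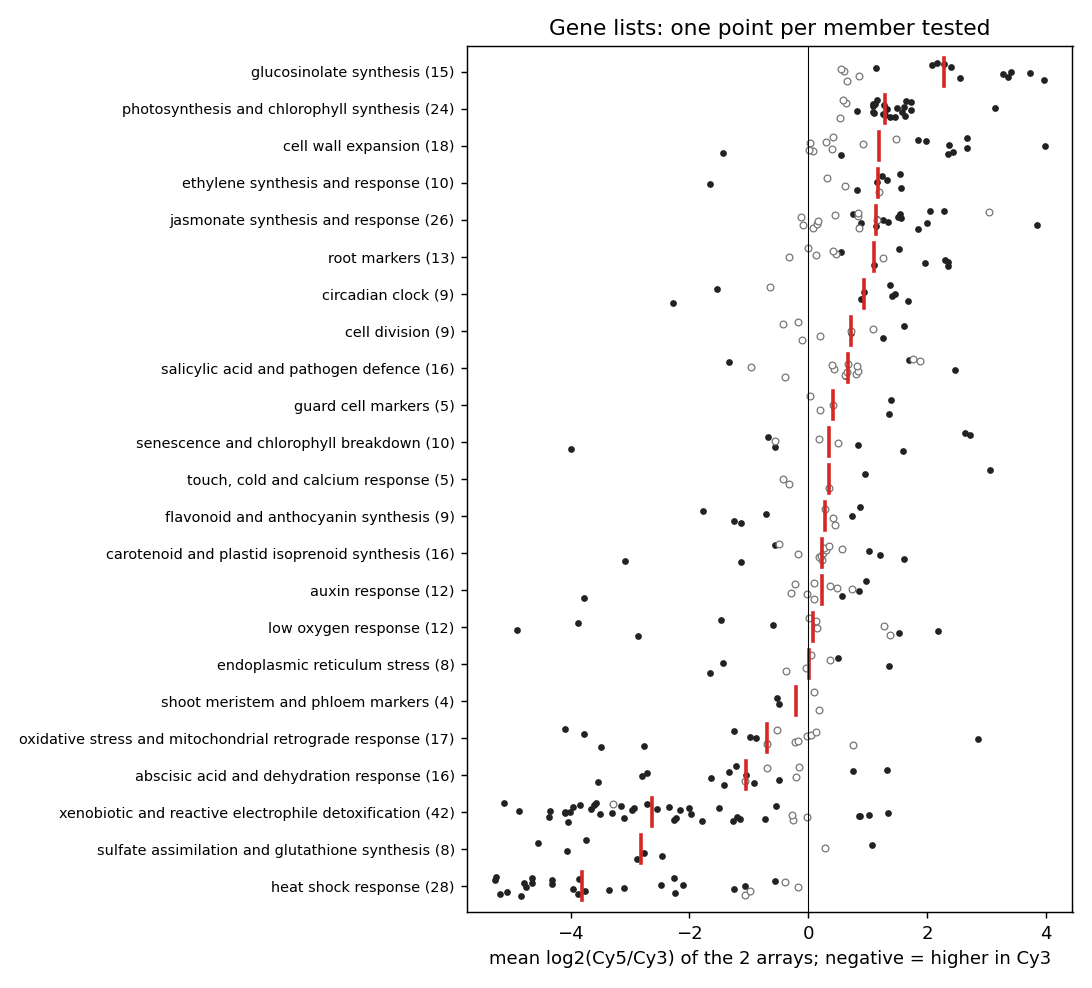
Mean log2 Cy5/Cy3 ratio of each tested member of the 23 gene lists, 1 point per gene, filled where the gene passed an adjusted p of 0.05 in the limma fit over all genes and open where it did not, with the list's median as a red bar and the number of tested members in parentheses. The medians run from -3.81 (heat shock) to 2.28 (glucosinolate synthesis).

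The other 11 lists did not pass, and several held genes with large ratios in opposite directions. In the low oxygen list 5 of 12 members were higher in Cy3 and 2 in Cy5 (5 and 2 adjusted over the list alone; camera, adjusted p = 0.302). The fermentation enzymes ADH1 and PDC1 stood at -2.86 ± 0.01 and -3.87 ± 0.39, and HRE1, a relative of HRE2, at 2.19 ± 0.64. Its median (0.07, with -0.36 on replicate 1 and 0.35 on replicate 2) and mean (-0.58) differ in sign, and the test pointed to Cy3. Among 9 clock genes, 2 were higher in Cy3 and 6 in Cy5 (3 and 6 adjusted over the list alone; camera, adjusted p = 0.276). The morning gene CCA1 stood at -2.27 ± 0.46, and the evening genes ELF4 and LUX at 1.68 ± 0.11 and 1.41 ± 0.10. Other probes gave -1.41 for CCA1 and 1.35 and 0.73 for LUX. The senescence list held DIN2 (-4.00 ± 0.000773) and SEN1 (2.73 ± 0.08), with 3 members higher in Cy3 and 4 in Cy5 of 10 (3 and 4 adjusted over the list alone; camera, adjusted p = 0.683). Carotenoid and plastid isoprenoid genes, which include the route to zeaxanthin, were higher in Cy3 for 3 and in Cy5 for 3 of 16 members (3 and 3 adjusted over the list alone; camera, adjusted p = 0.528). With median centring 2 were higher in Cy3 and 10 in Cy5, with a median of 0.84 against 0.45 for all genes. The carotene hydroxylases BCH2 and BCH1, which make zeaxanthin, stood at -3.08 ± 0.62 and -1.14 ± 0.13, and DXS, the entry enzyme of plastid isoprenoid synthesis, at 1.21 ± 0.20.

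Flavonoid genes were higher in Cy3 for 4 and in Cy5 for 2 of 9 members (4 and 2 adjusted over the list alone; camera, adjusted p = 0.668), with FLS1 at -1.77 ± 0.48 and chalcone synthase (CHS) at -1.25 ± 0.31. The median of the list (0.28, with 0.03 on replicate 1 and 0.50 on replicate 2) and its mean (-0.23) differ in sign, and the test pointed to Cy3. Its numbers in Cy3 and Cy5 became 4 and 5 with the Agilent processed signals and 2 and 2 with median centring. With median centring the median of all genes was 0.45. In the auxin list, where median (0.24) and mean (-0.01) also differ in sign and the test pointed to Cy5, 1 member was higher in Cy3, the auxin-conjugating GH3.3 (-3.78 ± 0.22), and 3 of 12 in Cy5 (1 and 3 adjusted over the list alone; camera, adjusted p = 0.528). Here the numbers became 2 and 7 with the Agilent processed signals and 1 and 5 with median centring. Endoplasmic reticulum stress genes were split 2 and 2 of 8 (2 and 2 adjusted over the list alone; camera, adjusted p = 0.683), with the transcription factor BZIP60 at -1.44 ± 0.16 and the chaperone BIP3 at 1.36 ± 0.18. Here too the median (0.01, with 0.14 on replicate 1 and -0.12 on replicate 2) and mean (-0.15) differ in sign, and the test pointed to Cy3. Salicylic acid and defence genes were higher in Cy3 for 1, PR5 (-1.33 ± 0.20), and in Cy5 for 3 of 16 members (1 and 0 adjusted over the list alone; camera, adjusted p = 0.276), among them NIMIN-2 with a wide spread (2.47 ± 1.33). The numbers in Cy3 and Cy5 became 1 and 9 with median centring and 3 and 6 with the Agilent processed signals. Of 9 cell division genes, 3 were higher in Cy5 (5 in Cy5 and 1 in Cy3 adjusted over the list alone; camera, adjusted p = 0.35), including the cytokinesis syntaxin KNOLLE (1.62 ± 0.33). Of 5 touch, cold and calcium genes, 2 were higher in Cy5, WRKY18 (3.06 ± 0.86) and CML24 (0.95 ± 0.30) (2 adjusted over the list alone; camera, adjusted p = 0.541). Of 4 shoot meristem and phloem markers, 2 were higher in Cy3 (2 adjusted over the list alone; camera, adjusted p = 0.528), STM at -0.53 ± 0.13 and KNAT1 at -0.49 ± 0.04, and with median centring neither passed and KNAT1 changed sign (0.01). Under that scaling 2 of the 4 were higher in Cy5 and none in Cy3, with a median of 0.35 against 0.45 for all genes. With members that were dim in one dye on both arrays at their bounds, list medians were 1.14 for ethylene, 1.13 for cell wall expansion, -0.53 for oxidative stress, 0.13 for auxin, 0.10 for flavonoid and -0.03 for touch and cold genes, and the same as before for the other lists.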

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

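The photosynthesis, root marker and salicylic acid patterns in this part were picked from the results, so their tests were not planned with the lists. The photosynthesis comparison without an intensity curve and the count of root markers were, with their expected outcomes, chosen only after the results were seen.

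Among 2033 probes with no gene locus that were bright enough to test and that no comparison used, 88 were at least 2-fold higher in Cy5 on both arrays and 50 were at least 2-fold higher in Cy3 on both. None of 153 negative control spots was well above background on either array.

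The count of genes at least 2-fold apart on both arrays was large, 1443 in the Cy5 and 1112 in the Cy3 direction. Noise of single arrays would put as many genes in opposite directions as in one direction, and 0.0391% of these genes lay in opposite directions. A dye bias set by the sequence of a probe would leave a second, non-overlapping probe of the gene with either sign, but the second probe had the same sign in 99.25% of 804 genes (95% confidence interval 98.4% to 99.7%, Clopper-Pearson), and 535 of them were 2-fold apart in the same way on it. After a fit on base counts of the probes was removed, 96.59% of the genes were still 2-fold apart on both arrays. An effect of the exposure may remain as a hypothesis, while a dye effect shared by all probes of a transcript and a difference between chambers stay open, since no array had the dyes exchanged.

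Photosynthesis genes were higher in Cy5, with a median of 1.29. A dye bias of bright probes would give intensity-matched lists a like median, and 0% of 10000 such lists reached it (highest 1.14). These lists were drawn from ratios that loess had already centred near 0 at each intensity (median 0.06). They show that the list stood apart from other genes of its intensity, and cannot exclude a dye bias of bright probes. A loess curve bent at high intensity would take the difference away when no curve is fitted, but with each array centred on its median the list lay 1.646 above the median of all genes, against 1.234 with loess. The comparison without a curve argues against the loess curve as the source, while a dye bias of bright probes stays open. A lower transcript level in safranal-exposed leaves may remain as a hypothesis if Cy3 is the safranal channel, and a different share of green tissue in the RNAs was not tested.

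Root markers were higher in Cy5, with a median of 1.11. A larger share of root in the Cy5 RNA was taken to shift all markers alike, and 3 of the 13 (PHO1, PLT1 and WOX5) lay below 0.55, the midpoint between 0 and that median, by more than their SD. Dim markers may not show the full shift, since 3 of the 13 were dim in 1 dye on both arrays. With an offset of 0 the list's median was 1.42. The number of markers below 0.55 falls between the bounds set for and against this explanation, so that a larger share of root and a change of root genes cannot be told apart. All 24 photosynthesis genes lay on the same Cy5 side, whereas a larger share of root alone could be expected to lower them.

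The median difference of the 16 salicylic acid and defence genes between the arrays (replicate 2 minus replicate 1) was 1.3, with all 16 higher on replicate 2, and 0% of 10000 intensity-matched lists differed as much (highest 0.49). Loess had centred both arrays at each intensity before these lists were drawn (median difference 0.01). The difference was the largest among the gene lists and was tested on the values it was picked from, which the draw does not allow for. Other lists differed between the arrays as well. The median difference was -0.71 for detoxification genes (6 of 42 higher on replicate 2) and -0.40 for photosynthesis genes (2 of 24). It was 0.69 for root markers (10 of 13). The draw shows only that the salicylic acid and defence genes stood apart from others of like intensity.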

How the results depend on the processing

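All alternatives in this part were planned. The numbers of genes higher in Cy5 and in Cy3 (3789 and 3069) became 6449 and 5189 without background correction, 2100 and 1673 with an offset of 0, 9004 and 1370 with median centring, and 0 and 0 both with scaling between arrays (5141 genes at an unadjusted p under 0.05 in limma) and with an ordinary 1-sample test (3576). Under the other alternatives they stayed within 1.5 times, though only 4450 of the 6858 genes that passed also did so with the Agilent processed signals. The numbers at least 2-fold apart on both arrays (1443 and 1112) became 2956 and 1849 with the Agilent processed signals, 2953 and 1848 with the Agilent log ratio, 2949 and 1843 with the deposited table and 3391 and 540 with median centring. With 1 array left out, the numbers 2-fold apart on the other ranged from 1696 to 2525 in Cy5 and from 1216 to 1720 in Cy3. They could not be lower than on both, since fewer arrays had to agree. The higher numbers were those of replicate 2, whose log2 ratios had the wider spread over genes (SD 1 against 0.81). For single genes, leaving 1 array out says nothing about stability, since with 2 arrays each value lies within the SD of the mean by construction. The spike-in slope of 0.904 became 0.9803 without background correction, 0.9684 with processed signals and 0.9683 with the log ratio.

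Among the 121 named genes, signs turned for SUC2 (-0.01616 with processed signals, -0.01553 with the log ratio and the deposited table) and, with median centring, for MCM5 (0.1238), KNAT1 (0.01127) and CBF2 (0.04976). Of the 6858 genes that passed, 389 had the opposite sign with median centring. The number was 16 with processed signals, 16 with the log ratio, 17 with the deposited table and 1 with the mean over a gene's probes. The camera direction of uncalled lists turned for carotenoid genes (medians -0.143, -0.1438 and -0.1437 with processed signals, log ratio and deposited table) and flavonoid genes (1.064, 1.064 and 1.065), for auxin (0.4555 with median centring, -0.1231 with a filter on both dyes) and for senescence (0.1881 with outlier spots kept). With fry the auxin list, at its unchanged median of 0.237, turned as well. Of the 11 called lists, ethylene was lost with processed signals, log ratio, deposited table and median centring, cell wall and root markers with median centring, and all 11 with an estimated correlation and with fry. The last 2 tests rest on 1 residual degree of freedom, so losing a call there does not show that a list is unchanged. Calls were gained by salicylic acid and low oxygen genes (4 alternatives each) and guard cell markers (2). Except where a smaller number of arrays is given, the cause was not tested. Of the named genes, 4 were dim in Cy3 on both arrays, and against the floor for dim signals the ratios were at least 4.80-fold for COBL9, 1.89-fold for SAUR15 and 1.39-fold for CYP71A13, while CBF1 did not exceed the floor.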

Other observations

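The tests of gene families in this part were chosen only after the results were seen. The test of the second clock list was prompted by genes already seen in the first, which also set its direction.

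Of 110 gene families taken from the array descriptions, with at least 10 tested genes each, 12 passed an adjusted p of 0.05 with limma camera, 10 toward Cy5 and 2 toward Cy3, and none passed with an estimated correlation (adjusted p = 0.891 for each). The former test takes genes as the replicates, and the latter rests on 1 residual degree of freedom and has little power. Peroxidases, which include 3 of the genes with the largest ratios, were higher in Cy5 for 19 of 34 genes and in Cy3 for 3, with a median of 1.45 (0.92 on replicate 1 and 1.79 on replicate 2; limma camera, adjusted p = 0.00194). AT5G64120 stood at 3.33 ± 0.48 and AT2G34060 at 1.74 ± 0.11, and AT1G68850 lay on the other side at -2.50 ± 0.36. In the family of xyloglucan transferases, which holds XTH16 of the cell wall list, 5 of 11 genes were higher in Cy5, among them XTH6 (3.45 ± 0.11) and XTH7 (2.22 ± 0.33). Pectate lyases were higher in Cy5 for 7 of 14 genes and extensin-like proteins for 8 of 12, with none higher in Cy3 in either family. Root markers, with a median of 1.11, and the root hair gene RHS13 lay on the same Cy5 side as these families. Leucine-rich repeat transmembrane kinases were higher in Cy5 for 28 of 75 genes and in Cy3 for 6, such as AT5G63410 at 2.97 ± 0.18 and AT4G34220 at 2.42 ± 0.23 in Cy5. Their medians lay above 0 under each scaling alternative.

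Mitochondrial substrate carriers were higher in Cy3 for 10 of 36 genes and in Cy5 for 1, with a median of -0.30 (limma camera, adjusted p = 0.0212). With median centring 5 were higher in Cy3 and 12 in Cy5, with a median of 0.11 against 0.45 for all genes. Among them mSFC1, a succinate and fumarate carrier, stood at -3.46 ± 0.15 and the dicarboxylate carrier DIC3 at -2.95 ± 0.45. Protein phosphatases of type 2C came under 2 descriptions that went opposite ways, so that no direction holds for the class. Under the first, 9 of 26 genes were higher in Cy3 and 2 in Cy5, with a median of -0.39 (limma camera, adjusted p = 0.0481). With median centring the numbers were 6 and 8, with a median of 0.12 against 0.45 for all genes. Under the second, 2 of 12 genes were higher in Cy3 and 6 in Cy5, with a median of 0.50 (limma camera, adjusted p = 0.707).

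In the clock list the morning gene CCA1 and the evening genes ELF4 and LUX lay on opposite sides. Of all 9 members, 2 were higher in Cy3 and 6 in Cy5, and that list was not tested by phase. A shift in clock phase between the RNAs would put other morning genes on the Cy3 side of evening genes, and in a second list of 15 genes, written before its values were examined, the mean was -0.71 for 10 morning and 1.71 for 5 evening genes (exact one-sided permutation test over 3003 arrangements, p = 0.000999). The difference was -2.41, lay between -2.63 and -2.33 under the alternatives that keep both arrays, and was -1.93 on replicate 1 and -2.90 on replicate 2. In limma 3 of the 10 morning genes passed, all toward Cy3, such as RVE2 at -1.56 ± 0.28, and 4 of the 5 evening genes, all toward Cy5, such as GRP7 at 2.90 ± 0.03. The morning genes COL2 (0.65 ± 0.57) and AT3G54500 (0.25 ± 0.31) and the evening gene BOA (-0.03 ± 0.42) lay on the other side and did not pass. Genes are not independent replicates, so the test covers the choice of genes and not the spread between seedlings. A shift in phase, from the exposure or from a different time of harvest, may account for the order of these genes, and which of the sources it is was not tested.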
